A study of Homo sapiens with 29 samples.

How the data were processed

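The series holds 29 samples. RNA was sequenced from 27 libraries in 9 groups of 3, and the remaining samples are a chromatin immunoprecipitation (ChIP) of NR0B1 and its input, with 1 library each. Per the labels, the knockdown libraries came from H460 and H2122 cells that carried short hairpin RNAs (sh) against GFP (the control), NRF2, NR0B1 or SNW1, and polyadenylated RNA was taken after 72 h in H460 and 24 h in H2122. Compound-treated H460 cells received 30 µM of BPK29 or BPK9, or the solvent DMSO, for 12 h. For the ChIP, cells were fixed with 1% formaldehyde for 15 min and 100 µg of chromatin was used, per the labels' protocols.

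The authors deposited one table of values named FPKM for 23710 gene symbols over all 27 RNA libraries. The name stands for fragments per kilobase of transcript, scaled to the mapped fragments. The depth scaling behind the deposited values instead closely follows median-ratio factors, as given below. Per the submitters' processing notes, STAR, featureCounts, DESeq2, Bowtie2, HOMER and the human build hg19 were used; versions, the role of each tool, the annotation, filters and the strand setting are not given in the sources used here. For the ChIP, the authors deposited a list of peak positions, whose score is the same in every line, so the file ranks no peak. Gene symbols were used as the table gives them, and 28 symbols that a spreadsheet reads as dates hold no value in the compound columns.

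The depth was recovered from the FPKM values themselves. Low values of a gene are whole multiples of what 1 read is worth in a library, and steps shared by the libraries gave whole reads for 100% of the 12938 genes tested in the knockdown columns and 100% of the 11461 tested in the compound columns (tolerance 0.02 reads). These sums came to 16709850 to 24613404 reads per knockdown library and 19077517 to 24824508 per compound library. The recovered reads were compared with standard scalings: the deposited knockdown columns follow median-ratio factors over the 18 libraries to within 0.00621%, and the compound columns follow them over their 9 libraries to within 1.49%. On simulated tables, the recovery found the reads of 100% of 1500 genes and the lengths of 100% of 1470 genes.

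The same steps give the gene length behind each value. Lengths in the compound columns differ from those in the knockdown columns gene by gene: of 12059 genes with both, 3 were equal and 53.5% were over 2 fold apart. For this reason levels in the compound groups are given as RPM (recovered reads of a gene, scaled to one common library total), and no FPKM level is compared between the knockdown and compound columns. A wrong length does not move a ratio between libraries, but it shifts which genes pass the minimum level and how much the pseudocount shrinks a fold change.

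Every comparison used limma on log2(FPKM + 1), with a mean-variance trend in the moderated variance. Genes with at least 1 FPKM in at least 3 of the libraries fitted were kept, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of low genes, and their errors are standard errors (SE). The 12 H460 knockdown libraries were fitted together, as were the 6 H2122 libraries and the 9 compound libraries. A test of the difference between the NRF2 knockdowns of the 2 lines (an interaction term) used the 6 H2122 libraries and the H460 shGFP and shNRF2 libraries. Each fit was checked on simulated data with known changes. At a simulated change of 1.5 fold, the fits found 90% of 50 changed genes in the H2122 comparison, 88% in the BPK29 and BPK9 comparisons against DMSO, and 64% in the interaction.

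Before the data were examined, 24 gene lists were fixed: NRF2 targets in 3 lists (glutathione and thioredoxin, NADPH and pentose phosphate, detoxification and efflux), ATF4 and serine synthesis, heat shock, endoplasmic reticulum chaperones, metallothioneins, aryl hydrocarbon receptor targets, cholesterol synthesis, mitosis, DNA replication, p53 targets, interferon response, NF-kB and chemokines, hypoxia and glycolysis, immediate early genes, ribosome biogenesis, spliceosome, steroid hormone synthesis, epithelial genes, mesenchymal genes, autophagy and lysosome, and markers of immune and of fibroblast and endothelial cells. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over lists and comparisons together.

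Named genes follow a rule set at the same time. It takes NR0B1, NFE2L2, SNW1, KEAP1 and RBM45; the 10 called genes with the largest change in each direction, if the treated and control libraries do not overlap and the mean of the higher group is at least 5 FPKM; and up to 4 members of each list. For overlaps it takes the 10 genes called in both with the largest summed change. Overlaps of calls were tested with one-sided Fisher's exact tests over the genes tested in both comparisons. Where comparisons share their control libraries, unchanged groups and their shared controls were simulated 20 times. All were drawn around the control means with the fitted spread, each gene independently, so an offset of the real control libraries is not reproduced.

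Alternatives set beforehand were a pseudocount of 0.1, no filter, rescaling to a common total (TPM), median-ratio scaling, no variance trend, a minimum fold of 1.5, the replicate number as a block, fits of only the groups compared, and leaving out each library in turn. The common total is a sum of deposited FPKM values, not of reads. In the compound columns this sum rests on the differing lengths, so it is no true TPM there. HDGF, divided by 27 bp, alone adds 34320 FPKM in DMSO replicate 1. Added after the data were seen were limma's voom on the recovered reads and, for the compounds, FPKM recomputed with each gene's own length. Analyses ran in R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks were counted and described only, since no annotation of hg19 was at hand, and ChIP and input have no replicate.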

Results

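Gene expression was measured by RNA sequencing in H460 and H2122, established human lung cancer lines that both carry mutations of KEAP1, the protein that marks the transcription factor NRF2 for degradation. The 27 RNA libraries form 9 groups of 3. In H460, groups with hairpins against GFP (control), NRF2, NR0B1 or SNW1 were sampled at 72 h, and in H2122 groups with hairpins against GFP or NRF2 were sampled at 24 h. A further 3 groups were H460 cells treated for 12 h with DMSO or with 30 µM of BPK29 or BPK9, which are named only by code. Binding of NR0B1 to chromatin in H460 was measured in 1 ChIP library beside 1 input. Per the series text, the aim was to find the genes that depend on NR0B1 in one line and on NRF2 in both. NR0B1 is an orphan nuclear receptor known as a corepressor, and SNW1 is a coregulator of transcription and splicing. Recovered depth was 16709850 to 24613404 reads in the knockdown libraries and 19077517 to 24824508 in the compound libraries. Values below are means with SD over 3 libraries, and fold changes are log2 with SE over 3 against 3 libraries. All p-values measure only the spread between these libraries, which may be technical replicates, since the labels do not say how they were made.

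The targeted transcripts fell in every knockdown. NFE2L2, which encodes NRF2, stood at 59.5, 58.4 and 57.5 FPKM in the H2122 shGFP libraries and at 27.5, 25.8 and 26.5 in the shNRF2 libraries. In H460 it stood at 44.0, 44.3 and 41.5 FPKM in shGFP and at 25.8, 26.8 and 27.9 in shNRF2. NR0B1 stood at 48.9, 45.7 and 48.2 FPKM in H460 shGFP, at 19.0, 18.3 and 17.2 in shNR0B1, at 9.0, 8.82 and 9.35 in shNRF2, and at 60.6, 60.2 and 58.8 in shSNW1. In H2122 it stood at 17.5, 19.9 and 18.7 FPKM in shGFP and at 0.983, 0.921 and 0.994 in shNRF2. SNW1 stood at 51.9, 52.3 and 49.3 FPKM in H460 shGFP and at 30.9, 34.3 and 31.5 in shSNW1. The log2 fold change of NFE2L2 after its own knockdown was -1.11 ± 0.0297 in H2122 (limma, Benjamini-Hochberg adjusted p = 6.51e-10) and -0.67 ± 0.0379 in H460 (adjusted p = 1.21e-09). NR0B1 fell by 1.34 ± 0.0414 after its own knockdown (limma adjusted p = 1.67e-11), and SNW1 fell by 0.65 ± 0.0428 after its own (limma adjusted p = 1.99e-08). NR0B1 thus fell further after NRF2 knockdown, with -3.32 ± 0.0531 in H2122 and -2.27 ± 0.0414 in H460, than the value after its own hairpin. NFE2L2 rose by 0.33 ± 0.0379 after NR0B1 knockdown and by 0.40 ± 0.0379 after SNW1 knockdown, and NR0B1 rose by 0.33 ± 0.0414 after SNW1 knockdown. KEAP1 changed by -0.68 ± 0.0316 in H2122 and by -0.15 in H460 after NRF2 knockdown and by 0.17 after SNW1 knockdown, with 0.01 after NR0B1 knockdown (limma adjusted p = 0.812). RBM45, an RNA-binding protein, fell by 0.24 in the H2122 NRF2 knockdown, by 0.22 in the NR0B1 knockdown and by 0.24 in the SNW1 knockdown, with 0.03 in the H460 NRF2 knockdown (limma adjusted p = 0.632). After rescaling to a common total, RBM45 was not called in any of these (-0.12, -0.10 and -0.16), KEAP1 was not called after H460 NRF2 knockdown (-0.06), and KEAP1 was called after NR0B1 knockdown (0.14).

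**Figure D1:**
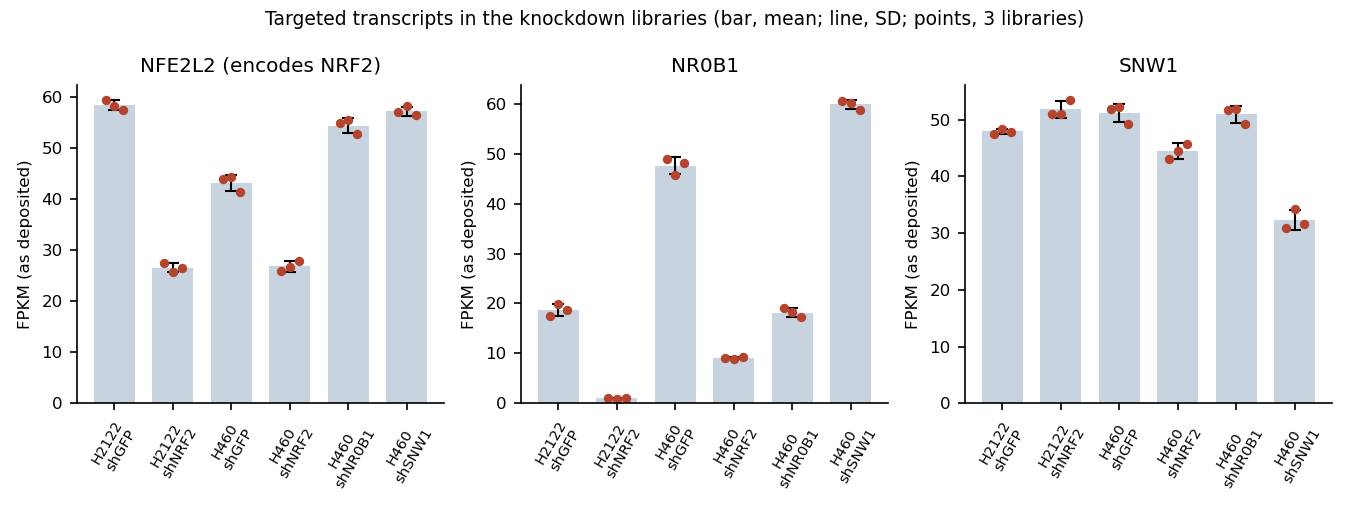
FPKM (y axis, linear, from 0) of NFE2L2, NR0B1 and SNW1 in the 6 knockdown and control groups, with bars for the mean, lines for the SD and points for the 3 libraries. Each transcript lies below its shGFP level where it was targeted, and NR0B1 lies lowest after NRF2 knockdown, at 0.966 in H2122 and 9.06 in H460.

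NRF2 knockdown in H2122 asks which genes depend on NRF2 in this line. Genes that NRF2 is known to control fell: AKR1B10, an aldo-keto reductase, went from 2911 ± 56.1 to 218 ± 9.25 FPKM (log2 fold change -3.73 ± 0.0315), FTL, the ferritin light chain, from 5353 to 788 FPKM (-2.76), and GCLM, a subunit of the enzyme that starts glutathione synthesis, by -2.78 ± 0.0308. All 20 tested glutathione and thioredoxin targets fell (median -1.41, limma camera, Benjamini-Hochberg adjusted p = 5.08e-09, and 0.0495 with an estimated correlation). These included HMOX1 (-2.70), heme oxygenase, and OSGIN1 (-2.47). Of 24 detoxification and efflux targets 22 fell and 2 rose (median -1.57, camera adjusted p = 5.96e-08; adjusted p = 0.0895 with an estimated correlation), with CBR3 at -2.97 and AKR1C1 at -3.15. Of 9 NADPH and pentose phosphate targets 8 fell and 1 rose (median -1.19, camera adjusted p = 0.000757; adjusted p = 0.135 with an estimated correlation), with ME1 at -2.03, MTHFD2 at -2.01 and TKT at -1.52. Proliferation genes fell as well: all 25 mitosis genes (median -1.65, camera adjusted p = 2.99e-10; adjusted p = 0.125 with an estimated correlation), such as the kinases PLK1 (-2.07) and AURKB (-2.08). So did all 27 DNA replication genes (median -1.54, camera adjusted p = 3.88e-10; adjusted p = 0.209 with an estimated correlation), such as CDC45 (-2.08) and RRM2 (-1.96).

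Other groups also moved in H2122. All 22 ribosome biogenesis genes fell (median -1.46, camera adjusted p = 2.75e-09; adjusted p = 0.0784 with an estimated correlation), such as FBL (-2.12) and NOP56 (-1.92). Glycolysis genes ENO1 (-1.77), GPI (-1.70) and LDHA (-1.60) were among 15 of 21 hypoxia and glycolysis genes that fell, with 5 higher (camera adjusted p = 0.00431; adjusted p = 0.145 with an estimated correlation). The heat shock list had 16 of 18 genes lower and 2 higher, with the chaperonins HSPD1 (-2.02) and HSPE1 (-1.53) falling most (camera adjusted p = 4.76e-05; adjusted p = 0.13 with an estimated correlation). Interferon response genes rose in 16 of 19 cases and fell in 2 (median 1.11, camera adjusted p = 0.00197; adjusted p = 0.0895 with an estimated correlation). These included IFI27 (2.00), IRF9 (1.76) and OAS1 (1.68). NF-kB and chemokine genes rose in 13 of 17 cases and fell in 4 (median 0.43, camera adjusted p = 0.047; adjusted p = 0.176 with an estimated correlation). These included TNFAIP2 (1.87) and IL1B (1.56). Epithelial genes rose in 15 of 18 cases and fell in 2 (median 0.55, camera adjusted p = 0.00139; adjusted p = 0.175 with an estimated correlation). These included the mucin MUC1 (2.51) and the transcription factor ELF3 (1.78). The salivary cystatins CST1, CST2 and CST4 had the largest rises, for example CST4 from 6.74 ± 0.223 to 133 ± 2.2 FPKM (4.11 ± 0.0299), and these near-identical genes may share reads, as may AKR1C1 and AKR1B10 with their close copies. TMPRSS2, a membrane serine protease, rose by 4.02 ± 0.0441, while EPGN, a growth factor of the EGF family, fell by 3.29 and the neuronal gene CPLX2 fell by 3.55. All 3 tested markers of immune cells rose, namely LYZ (2.18, from 0.359 to 5.16 FPKM), CD79A (2.08) and CD68 (1.07, from 45.5 to 96.5 FPKM), and the fibroblast marker COL1A1 rose by 0.47.

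In all, limma called 10228 of 11710 genes in H2122 at an adjusted p under 0.05, 5715 higher and 4513 lower, of which 4891 changed by at least 1.5 fold. The counts were 6577 higher and 3801 lower after rescaling to a common total, which shifts the median of all genes by 0.149, and 5057 and 5092 with median-ratio scaling. Which direction holds more genes therefore depends on the scaling. No call by camera was made for ATF4 and serine synthesis (8 higher and 14 lower of 22, adjusted p = 0.0636), p53 targets (18 and 4 of 25, 0.0506), metallothioneins (1 and 4 of 5, 0.114), aryl hydrocarbon receptor targets (3 and 3 of 6, 0.873), immediate early genes (10 and 3 of 15, 0.356), mesenchymal genes (6 and 3 of 10, 0.335) or autophagy and lysosome (14 and 5 of 20, 0.275). Nor was one made for endoplasmic reticulum chaperones (6 higher and 8 lower, or 10 and 7 after rescaling to a common total), cholesterol synthesis (8 and 12, or 11 and 10) or the spliceosome (8 and 14, or 12 and 11). Counts adjusted over the list alone were the same, except 7 higher and 11 lower for cholesterol synthesis and 7 higher and 3 lower for mesenchymal genes. Over all comparisons, the camera calls that hold with an estimated correlation are glutathione targets after both NRF2 knockdowns, detoxification targets after the H460 one, DNA replication and immediate early genes for BPK29 against DMSO and against BPK9, and 4 lists in the difference between lines.

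NRF2 knockdown in H460 asks which genes depend on NRF2 in the other line. TXNRD1, thioredoxin reductase, went from 515 ± 8.72 to 212 ± 3.21 FPKM (log2 fold change -1.27 ± 0.0269), SRXN1, sulfiredoxin, from 363 to 139 FPKM (-1.38 ± 0.0295), and the aldo-keto reductase AKR1C2 fell by 1.60 ± 0.0287, with reads possibly shared with its copies. Of 19 glutathione and thioredoxin targets 17 fell and 2 rose (median -0.78, limma camera, Benjamini-Hochberg adjusted p = 9.42e-06, and 0.0495 with an estimated correlation). Of 23 detoxification and efflux targets 20 fell and 1 rose (median -0.77, camera adjusted p = 2.37e-06, and 0.0495 with an estimated correlation). NADPH and pentose phosphate targets fell in 8 of 9 cases and none rose (camera adjusted p = 0.00083; adjusted p = 0.0587 with an estimated correlation), with MTHFD2 at -1.86 and PPAT at -1.14. NQO1, a quinone reductase and a known NRF2 target, was one of the exceptions and rose by 0.31 ± 0.0273. Mitosis genes fell in 25 of 25 cases (median -1.47, camera adjusted p = 1.99e-10; adjusted p = 0.136 with an estimated correlation) and DNA replication genes in 26 of 27 (median -1.67, camera adjusted p = 2.99e-10; adjusted p = 0.105 with an estimated correlation), among them UBE2C (-1.75), AURKB (-1.80) and E2F1 (-2.11).

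Cholesterol synthesis genes fell in 19 of 23 cases in this knockdown and 1 rose (median -0.66, camera adjusted p = 2.34e-05; adjusted p = 0.0986 with an estimated correlation). These included ACAT2 (-1.70), INSIG1 (-1.45) and IDI1 (-1.29). ATF4 and serine synthesis genes fell in 16 of 22 cases and rose in 4 (camera adjusted p = 0.00378; adjusted p = 0.384 with an estimated correlation). These included CHAC1 (-1.84), PHGDH (-1.54) and PSAT1 (-1.36). Endoplasmic reticulum chaperone genes rose in 16 of 18 cases and fell in 2 (median 0.73, camera adjusted p = 8.29e-05; adjusted p = 0.153 with an estimated correlation). These included CALR, from 402 to 932 FPKM (1.21), and HSPA5, from 344 to 730 FPKM (1.08). Autophagy and lysosome genes rose in 16 of 20 cases and fell in 3 (camera adjusted p = 0.00236; adjusted p = 0.0627 with an estimated correlation). These included WIPI1 (1.87) and GABARAPL1 (1.66). Ribosome biogenesis genes fell in 21 of 22 cases (camera adjusted p = 1.16e-06; adjusted p = 0.0564 with an estimated correlation), with FBL at -1.50. The heat shock list had 13 of 20 genes lower and 1 higher (camera adjusted p = 0.00191; adjusted p = 0.0784 with an estimated correlation), with HSP90AA1 at -1.12. Of 16 NF-kB and chemokine genes 10 fell and 4 rose (camera adjusted p = 0.0413; adjusted p = 0.247 with an estimated correlation), such as IL8, from 273 to 73.6 FPKM (-1.87). Of 22 hypoxia and glycolysis genes 14 fell and 5 rose (camera adjusted p = 0.0391; adjusted p = 0.375 with an estimated correlation), with carbonic anhydrase CA9 at -2.12. Among the largest changes were those in FURIN, a proprotein convertase, from 23.5 ± 2.36 to 274 ± 11.5 FPKM (3.49 ± 0.0566), SDC2 (3.35), PCDH20 (3.25), the pentraxin PTX3 (-3.62 ± 0.0803) and VGF, a neuropeptide precursor (-3.39 ± 0.0501). The list of fibroblast and endothelial markers had 4 higher and 1 lower of 6 (camera adjusted p = 0.148), with DCN at 2.66 and COL3A1 at -0.68, and of the immune markers CD14 rose by 0.49 and CD68 fell by 0.21.

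Limma called 9532 of 11938 genes in this comparison at an adjusted p under 0.05, 4878 higher and 4654 lower, of which 3746 changed by at least 1.5 fold. The counts were 5532 and 4016 after rescaling to a common total and 4650 and 4929 with voom, so the larger direction depends on the scaling. Lists without a camera call were p53 targets (9 higher and 12 lower of 25, or 10 and 10 after rescaling to a common total), interferon response (11 and 5 of 20, adjusted p = 0.395), immediate early genes (4 and 9 of 15, 0.0876), spliceosome (8 and 16 of 28, 0.154), epithelial genes (2 and 8 of 11, 0.189), mesenchymal genes (11 and 3 of 16, 0.0757) and metallothioneins (1 and 3 of 5, 0.268). Counts adjusted over the list alone were the same for every list.

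**Figure D2:**
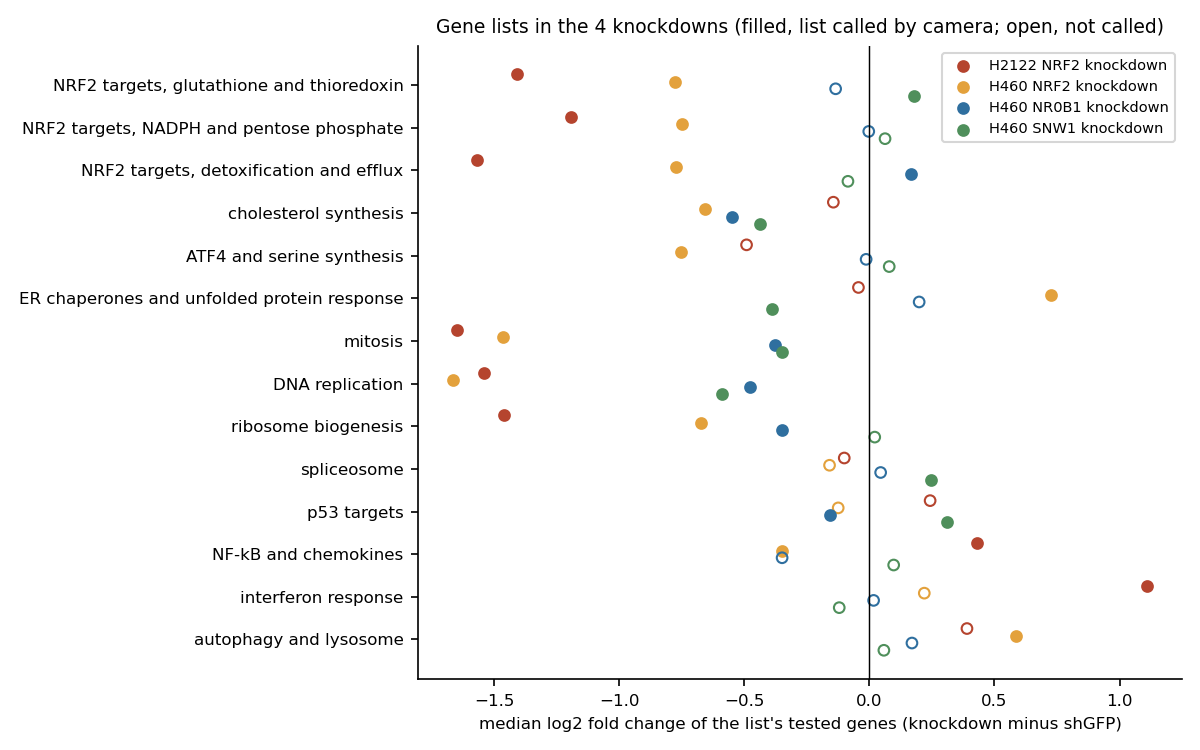
Median log2 fold change of each gene list (x axis) in the 4 knockdowns, with lists on the y axis, and filled points for lists called by camera at the preset correlation. Mitosis genes lie at -1.65 and -1.47 after NRF2 knockdown in H2122 and H460 and at -0.38 and -0.35 after NR0B1 and SNW1 knockdown.

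The difference between the lines was tested directly with an interaction term. Most of the called genes moved the same way in both: 3190 were higher in both lines, against 1968 for independent lists, and 3116 were lower in both, against 1775 (odds ratios 8.0 with a 95% interval of 7.31 to 8.75, and 10.2 with 9.35 to 11.2, one-sided Fisher's exact tests over 10731 genes). Fold changes correlated across genes, which are not independent replicates (Pearson's r 0.653, Spearman's rho 0.649). Shared changes included the histone gene HIST1H2AC (2.83 in H2122 and 2.11 in H460), FURIN (1.04 and 3.49) and the complexin CPLX2 (-3.55 and -2.63). Glutathione and thioredoxin targets fell further in H2122 (18 of 20 genes with a lower and 2 with a higher interaction, limma camera, Benjamini-Hochberg adjusted p = 1.82e-06, and 0.0495 with an estimated correlation), for example GCLM by a difference of -1.58 ± 0.0703. Detoxification targets had 17 of 24 lower and 6 higher (camera adjusted p = 0.00054; adjusted p = 0.105 with an estimated correlation), for example CBR1 at -2.28 ± 0.0418. Ribosome biogenesis genes fell further in H2122 (19 of 22, camera adjusted p = 1.94e-07, and 0.0495 with an estimated correlation), for example NCL, nucleolin, at -1.08 ± 0.0517. Interferon genes (17 of 22 higher, 2 lower, camera adjusted p = 0.000467) and NF-kB genes (16 of 19 higher, 3 lower, camera adjusted p = 0.000138) were higher in H2122 relative to H460, both with an adjusted p of 0.0495 with an estimated correlation. CXCL1, a chemokine, rose by 1.21 in H2122 and fell by 1.24 in H460, and PLAU, the urokinase protease, rose by 1.57 and fell by 1.87.

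Further lists differed between the lines at the preset correlation. Endoplasmic reticulum chaperones had 13 of 18 lower and 2 higher interactions (camera adjusted p = 6.16e-05; adjusted p = 0.11 with an estimated correlation), for example HSPA5 at -1.34, and cholesterol synthesis had 18 of 23 higher and 3 lower (camera adjusted p = 0.000835; adjusted p = 0.0627 with an estimated correlation), for example INSIG1 at 1.31. Epithelial genes were higher in 17 of 18 cases (camera adjusted p = 7.56e-06; adjusted p = 0.0895 with an estimated correlation), and p53 targets in 19 of 25, with 4 lower (camera adjusted p = 0.00272; adjusted p = 0.196 with an estimated correlation). Autophagy genes had 13 of 20 lower and 4 higher (camera adjusted p = 0.00359; adjusted p = 0.0691 with an estimated correlation), and mitosis genes 18 of 25 lower (camera adjusted p = 0.000835; adjusted p = 0.357 with an estimated correlation). Immediate early genes had 11 of 15 higher and 3 lower (camera adjusted p = 0.0193; adjusted p = 0.26 with an estimated correlation), and heat shock genes 12 of 20 lower and 3 higher (camera adjusted p = 0.0243; adjusted p = 0.0998 with an estimated correlation). Adjusted over the list alone, the counts were the same except 7 higher and 17 lower for detoxification targets. Markers of other cell types differed too, with LYZ at 2.14 and DCN at -2.62. Limma called 9168 of 12798 genes at an adjusted p under 0.05, 4782 higher and 4386 lower in H2122 relative to H460, and 3629 by at least 1.5 fold. The lines were sampled at 24 h and 72 h, so line and time cannot be told apart in this test.

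**Figure D3:**
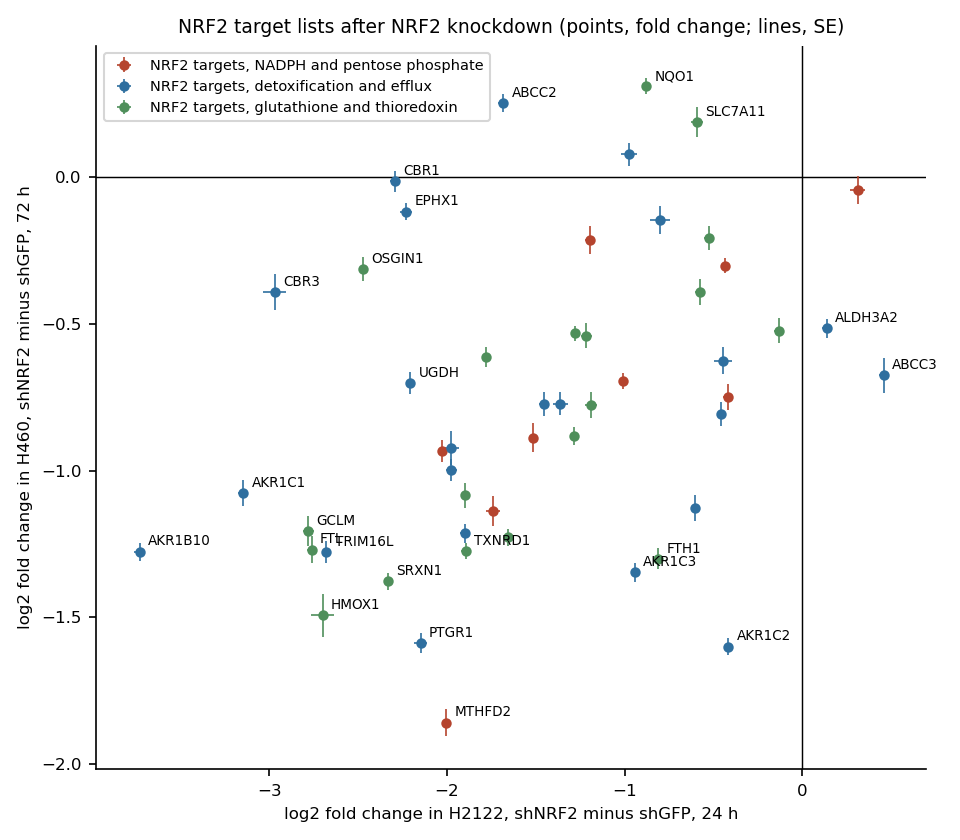
Log2 fold change of each NRF2 target after NRF2 knockdown in H2122 at 24 h (x axis) and H460 at 72 h (y axis), with SE as lines and colours for the 3 lists. Most points lie below 0 on both axes, and NQO1 lies at -0.88 in H2122 and 0.31 in H460.

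NR0B1 knockdown in H460 asks which genes depend on NR0B1. FGFRL1, a decoy receptor of the fibroblast growth factor family, rose from 5.27 ± 0.267 to 44.4 ± 0.895 FPKM (log2 fold change 2.85 ± 0.0439), and CHGA, chromogranin A of secretory granules, rose from 4.2 to 26.5 FPKM (2.41 ± 0.0578). VGF fell from 42.3 ± 1.58 to 5.09 ± 0.283 FPKM (-2.83 ± 0.0501), and PLAU fell from 59.9 to 12.1 FPKM (-2.22 ± 0.037). On the scale from shGFP (0) to the mean of the 3 H460 knockdowns (1), the DMSO libraries lay at 1.01 for FGFRL1, 0.568 for CHGA, 1.04 for VGF and 0.705 for PLAU. Cholesterol synthesis genes fell in 18 of 23 cases and rose in 3 (median -0.55, limma camera, Benjamini-Hochberg adjusted p = 8.29e-05; adjusted p = 0.11 with an estimated correlation). These included IDI1 (-1.68), MSMO1 (-1.14) and INSIG1 (-0.83). DNA replication genes fell in 24 of 27 cases and rose in 1 (median -0.48, camera adjusted p = 1.77e-06; adjusted p = 0.194 with an estimated correlation). These included thymidylate synthase TYMS (-1.37) and RFC3 (-1.26). Mitosis genes fell in 21 of 25 cases and rose in 1 (camera adjusted p = 7.54e-05; adjusted p = 0.349 with an estimated correlation), with TPX2 at -0.85. Heat shock genes fell in 16 of 20 cases and rose in 2 (camera adjusted p = 0.000323; adjusted p = 0.0627 with an estimated correlation). These included the chaperones HSPA6 (-1.09) and HSP90AA1 (-0.81). Ribosome biogenesis genes fell in 19 of 22 cases and rose in 1 (camera adjusted p = 6.98e-05; adjusted p = 0.0691 with an estimated correlation), with NOLC1 at -0.67. Immediate early genes fell in 12 of 15 cases and rose in 2 (camera adjusted p = 0.00264; adjusted p = 0.194 with an estimated correlation), among them MCL1 (-1.08) and DUSP1 (-0.88).

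NRF2 targets went both ways after NR0B1 knockdown. Detoxification and efflux targets rose in 15 of 23 cases and fell in 4 (median 0.17, camera adjusted p = 0.0262; adjusted p = 0.176 with an estimated correlation), with AKR1B10 at 0.71 and ABCC3 at 0.74 but ALDH3A1 at -0.98. Glutathione and thioredoxin targets had 5 higher and 10 lower of 19 (camera adjusted p = 0.571), a split that became 9 and 5 after rescaling to a common total and 7 and 7 with voom. Within that list the cystine transporter SLC7A11 rose by 0.77 and NQO1 fell by 0.59 ± 0.0273, from 1267 ± 22 to 842 ± 17.9 FPKM. NADPH and pentose phosphate targets had 4 higher and 3 lower of 9 (camera adjusted p = 0.637), a median of -0.00 that became 0.13 after rescaling to a common total (5 and 3) and 0.08 with voom, and a mean of 0.02. Hypoxia and glycolysis genes rose in 13 of 22 cases and fell in 4 (camera adjusted p = 0.021; adjusted p = 0.346 with an estimated correlation). These included the glucose transporter SLC2A1 (0.76). P53 targets fell in 15 of 25 cases and rose in 4 (camera adjusted p = 0.0401; adjusted p = 0.367 with an estimated correlation), among them PLK2 (-0.85). Chemokines IL8 (-1.52), CXCL2 (-1.36) and CXCL1 (-1.27) fell, while IL1B of the same list rose by 1.21 (4 higher and 10 lower of 16, camera adjusted p = 0.153). Of the steroid hormone list, where 3 genes were tested, NR4A1 fell by 1.13 and ESRRA (-0.10) and NR4A2 (-0.08) did not pass the test. The collagen gene COL3A1 (0.88) and the monocyte marker CD14 (0.88, from 5.38 to 10.7 FPKM) rose.

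Limma called 8337 of 11938 genes in the NR0B1 comparison at an adjusted p under 0.05, 3946 higher and 4391 lower, of which 829 were higher and 854 lower by at least 1.5 fold. The share of higher calls was 47.3%, against 63.5% after rescaling to a common total (5286 higher and 3041 lower), which shifts the median of all genes by 0.127, and 57.4% with voom (4928 and 3659). Lists without a call were endoplasmic reticulum chaperones (11 higher and 4 lower of 18, camera adjusted p = 0.0541), interferon response (7 and 4 of 20), autophagy (10 and 7 of 20), mesenchymal genes (9 and 6 of 16, with a median of 0.22 and a mean of -0.03), spliceosome (10 and 7 of 28), metallothioneins (2 and 1 of 5) and, with a direction that turns with the scaling, ATF4 and serine synthesis (8 and 8 of 22) and epithelial genes (4 and 3 of 11). Counts adjusted over the list alone were the same except 7 higher and 3 lower for interferon response.

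SNW1 knockdown in H460 asks what this coregulator controls. CDKN1A, the cell cycle inhibitor p21, rose from 46 ± 1.07 to 131 ± 3.55 FPKM (log2 fold change 1.49 ± 0.041), EGR1, an immediate early transcription factor, from 1.72 ± 0.214 to 15.2 ± 0.626 FPKM (2.58 ± 0.0658), and CHGA from 4.2 to 36.8 FPKM (2.86 ± 0.0578). Spliceosome genes rose in 20 of 28 cases and fell in 1 (median 0.25, limma camera, Benjamini-Hochberg adjusted p = 1.1e-05; adjusted p = 0.0587 with an estimated correlation). These included RBM22, from 12.3 to 29.9 FPKM (1.21 ± 0.0424), PRPF3 (0.98) and PRPF8 (0.84). P53 targets rose in 15 of 25 cases and fell in 5 (median 0.31, camera adjusted p = 0.00123; adjusted p = 0.179 with an estimated correlation), with GDF15 at 1.12 and AEN at 0.91 but the death receptor FAS at -0.92. Immediate early genes rose in 9 of 15 cases and fell in 1 (camera adjusted p = 0.00986; adjusted p = 0.253 with an estimated correlation). These included JUNB (0.59). Glutathione and thioredoxin targets rose in 13 of 19 cases and fell in 3 (median 0.18, camera adjusted p = 0.0133; adjusted p = 0.111 with an estimated correlation), with HMOX1 at 1.45 ± 0.0747 (from 15.8 to 44.9 FPKM), GCLM at 0.60 and GCLC at 0.53. DNA replication genes fell in 25 of 27 cases and rose in 2 (median -0.59, camera adjusted p = 7.19e-07; adjusted p = 0.176 with an estimated correlation). These included GINS2 (-1.30) and E2F1 (-1.15). Mitosis genes fell in 19 of 25 and rose in 3 (camera adjusted p = 0.000193; adjusted p = 0.375 with an estimated correlation), with CDK1 at -0.80. Cholesterol synthesis genes fell in 21 of 23 cases and rose in 1 (camera adjusted p = 1.22e-05; adjusted p = 0.0895 with an estimated correlation). These included MSMO1 (-0.96) and INSIG1 (-0.94). Endoplasmic reticulum chaperone genes fell in 14 of 18 cases and rose in 2 (camera adjusted p = 0.000542; adjusted p = 0.194 with an estimated correlation). These included XBP1 (-0.61) and CALR (-0.55). The snoRNA genes SNORD33, SNORD43 and SNORD99 were among the largest rises, for example SNORD33 at 2.06, and they lie within host genes whose reads they may share. Of the markers of other cell types, CD14 fell by 0.82 (from 5.38 to 2.61 FPKM), PDGFRB by 0.54, KDR by 0.31 and COL3A1 by 0.24.

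Limma called 8020 of 11938 genes in the SNW1 comparison at an adjusted p under 0.05, 3671 higher and 4349 lower, of which 648 were higher and 821 lower by at least 1.5 fold. Higher calls made up 45.8%, against 58.6% after rescaling to a common total (4756 higher and 3356 lower) and 56.4% with voom (4684 and 3620). Detoxification targets had 8 higher and 10 lower of 23 (10 and 5 after rescaling to a common total, and a median of -0.09 beside a mean of 0.04), heat shock genes 5 and 8 of 20 (8 and 4), and hypoxia and glycolysis genes 7 and 9 of 22 (9 and 7), each without a camera call. NADPH targets (4 and 2 of 9), ribosome biogenesis (8 and 3 of 22), NF-kB (8 and 3 of 16), interferon response (3 and 9 of 20) and autophagy (10 and 8 of 20) had none either. Adjusted over the list alone, the counts were the same for the lists named here.

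The 3 knockdowns in H460 shared many of their changes. NR0B1 and NRF2 knockdown had 2711 higher genes in common, against 1612 for independent lists (odds ratio 5.90, 95% interval 5.42 to 6.42). They had 2898 lower genes in common, against 1712 (6.4, 5.89 to 6.96), while 608 and 852 went opposite ways, against 1538 and 1794. FURIN (1.26 after NR0B1 and 3.49 after NRF2 knockdown), FGFRL1 (2.85 and 1.53), VGF (-2.83 and -3.39) and PTX3 (-2.21 and -3.62) led the shared genes. On the scale from the shGFP libraries (0) to the mean of the knockdowns (1), the DMSO libraries of the same line lay at 1.01 for FGFRL1, 1.04 for VGF, 0.493 for PTX3 and -0.323 for FURIN. In this other H460 control, FGFRL1 and VGF thus lay near the mean of the knockdown libraries. NR0B1 and SNW1 knockdown had 2144 higher genes in common, against 1213 (odds ratio 5.04, 4.63 to 5.48). Lower in both were 2596, against 1600 (4.78, 4.41 to 5.18), while 648 and 569 went opposite ways, against 1438 and 1350. The shared genes were led by CHGA, FGFRL1 and CALB2, the gene of the calcium-binding protein calretinin. NRF2 and SNW1 knockdown had 2191 higher genes in common, against 1500, and 2429 lower, against 1695 (odds ratios 3.07 and 3.05). Opposite ways went 1245 and 783, against 1777 and 1431. At a minimum of 1.5 fold these were 142 and 26, against 135 and 96.6. All 3 comparisons use the same shGFP libraries. Unchanged groups and controls simulated around the shGFP means shared 0.1, 0 and 0 calls on average. This does not test an offset of the real shGFP libraries. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.51, 0.506 and 0.326 for the 3 pairs in this order, beside 0.499, 0.493 and 0.501 in the simulations. Their covariances were 0.139, 0.0849 and 0.0842, beside simulated ones of 0.00289, 0.00284 and 0.00292, differences of 0.136, 0.082 and 0.0812. Part of the excess may come from the shared controls, and fits that split the shGFP libraries between the comparisons were not run.

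BPK29 at 30 µM for 12 h moved stress and proliferation genes in H460. Levels are given as RPM (reads scaled to a common library total), since the gene lengths behind the FPKM values of the compound columns differ gene by gene from those of the knockdown columns. The fold changes beside them are from log2(FPKM + 1) with the deposited scaling, so they need not equal the ratios of the RPM values. HMOX1 rose from 47.2 ± 1.72 to 107 ± 2.32 RPM (log2 fold change 1.07 ± 0.0324), ASNS, asparagine synthetase, from 72 ± 3.22 to 149 ± 4.62 (0.96 ± 0.0378), and CYP1B1, a known target of the aryl hydrocarbon receptor, from 457 to 917 RPM (0.93 ± 0.0354). ATF4 and serine synthesis genes rose in 12 of 21 cases and fell in 2 (median 0.23, limma camera, Benjamini-Hochberg adjusted p = 1.65e-05; adjusted p = 0.0627 with an estimated correlation), with ALDH1L2 at 0.99 and STC2 at 0.61. All 5 tested aryl hydrocarbon receptor targets rose (camera adjusted p = 0.000146; adjusted p = 0.0627 with an estimated correlation). These included AHRR (0.71) and TIPARP (0.37). Endoplasmic reticulum chaperones rose in 15 of 18 cases (median 0.15, camera adjusted p = 1.4e-06; adjusted p = 0.0564 with an estimated correlation), with HSP90B1 at 0.37 and HSPA5 at 0.31. Immediate early genes rose in 12 of 15 cases and fell in 1 (median 0.40, camera adjusted p = 3.75e-06, and 0.0495 with an estimated correlation), with JUNB at 0.80 and MCL1 at 0.59 but DUSP6 at -0.60. NF-kB genes rose in 11 of 16 cases and fell in 2 (camera adjusted p = 0.00389; adjusted p = 0.0774 with an estimated correlation), with NFKBIA at 0.43. Autophagy and lysosome genes rose in 14 of 20 cases and fell in 2 (camera adjusted p = 6.26e-05; adjusted p = 0.0691 with an estimated correlation), with ULK1 at 0.45. P53 targets rose in 10 of 23 and fell in 4 (camera adjusted p = 0.0231; adjusted p = 0.107 with an estimated correlation), with GDF15 at 0.98 and CDKN1A at 0.57. Heat shock genes fell in 17 of 20 cases and 1 rose (median -0.33, camera adjusted p = 3.19e-07, and 0.0668 with an estimated correlation). HSPA8 fell from 3960 to 2620 RPM (-0.66), as did the near-identical HSPA1A (-1.06) and HSPA1B (-0.95), but HSPA6 rose by 1.89. HSPA6 was divided by 282 bp here and by 2652 bp in the knockdown columns. In DMSO replicate 1 it stood at 4.36 FPKM as deposited and at 0.463 with its own length, so the size of its rise depends on the length used.

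Mitosis genes fell in 24 of 25 cases after BPK29 (median -0.34, camera adjusted p = 5.56e-10; adjusted p = 0.0784 with an estimated correlation). These included CDK1 (-0.44) and PLK1 (-0.39). DNA replication genes fell in 22 of 27 cases and 1 rose (median -0.19, camera adjusted p = 1.4e-06, and 0.0495 with an estimated correlation), with MCM7 at -0.77 and cyclin CCNE1 at 0.46. Cholesterol synthesis genes fell in 14 of 22 cases and rose in 2 (camera adjusted p = 0.00794; adjusted p = 0.0895 with an estimated correlation), with LSS at -0.45. Ribosome biogenesis genes fell in 13 of 22 and rose in 1 (camera adjusted p = 0.0103; adjusted p = 0.349 with an estimated correlation), with NPM1 at -0.28. NRF2 targets had no camera call: glutathione targets had 6 higher and 5 lower of 19 (adjusted p = 0.144), NADPH targets 1 and 4 of 9 (0.225), and detoxification targets 8 and 7 of 23 (0.271), with AKR1C1 at 0.54, ALDH3A1 at 0.52 and AKR1B10 at -0.42. NR0B1 itself had a log2 fold change of -0.07 ± 0.0241 (90.7 ± 2.01 against 91.4 ± 1.77 RPM, limma adjusted p = 0.0275), a call that depends on the scaling. It was not called after rescaling to a common total (-0.0036, limma adjusted p = 0.913), with median-ratio scaling (-0.05, 0.1) or with voom (-0.01, 0.754). Nor was it called without DMSO replicate 1 (-0.06), BPK29 replicate 2 (-0.05) or BPK29 replicate 3 (-0.08). RBM45 fell by 0.38 ± 0.047 (limma adjusted p = 0.000122), and SNW1 had -0.01 (limma adjusted p = 0.826), or 0.07 after rescaling to a common total. Interferon response genes had 1 higher and 6 lower of 16 (camera adjusted p = 0.148), with OAS3 at -0.66 and a median that is -0.00, or 0.05 after rescaling to a common total. Adjusted over the list alone, 13 ATF4 genes and 12 NF-kB genes rose, 3 NF-kB genes and 23 DNA replication genes fell, and 2 ribosome biogenesis genes and 7 glutathione targets rose; other counts named here were the same. Limma called 5777 of 11461 genes at an adjusted p under 0.05, 2418 higher and 3359 lower, of which 96 were higher and 175 lower by at least 1.5 fold. Higher calls made up 41.9%, against 63.6% after rescaling to a common total (3847 and 2202) and 61.3% with voom (3914 and 2476). The common total here sums FPKM values that rest on the differing lengths, while voom uses the recovered reads.

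BPK9 at the same dose and time left nearly all of these genes without a call. Limma called 1 gene, SNORA71A, a snoRNA with 0.13 against 0.423 RPM (log2 fold change -1.31 ± 0.0898, adjusted p = 0.000847), which lies within a host gene. This gene had too few reads for a length of its own. At an unadjusted p under 0.05 there were 1725 genes, voom called 238, and with each gene's own length limma called 57. The 95% interval of the fold change lay within 1.5 fold for 97.6% of the 11461 genes. With BPK29 only 271 genes changed by at least 1.5 fold, so this share does not set the compounds apart. For 256 of these 271 genes the BPK29 change lay beyond the BPK9 interval. Their median absolute log2 fold change was 0.731 with BPK29 and 0.107 with BPK9, and 199 had the same sign. They were picked by their BPK29 change, and both comparisons share the DMSO libraries. HMOX1 stood at 48.8 ± 0.431 RPM with BPK9 and 47.2 ± 1.72 with DMSO, ASNS at 69.1 against 72, and NR0B1 at 95.1 against 91.4 (limma adjusted p = 0.436). No list had a member called by limma on the deposited values. With voom 8 heat shock genes were called lower and 4 detoxification targets higher, other lists had at most 4 members called, and after rescaling to a common total 2 heat shock genes were called lower. Small shifts of whole lists passed camera at the preset correlation. Heat shock genes lay lower (median -0.07, camera adjusted p = 7.77e-07; adjusted p = 0.0691 with an estimated correlation; 1 higher and 10 lower adjusted over the list alone), and immediate early genes higher (median 0.05, camera adjusted p = 0.00137; adjusted p = 0.0627 with an estimated correlation; 5 higher alone). Ribosome biogenesis (camera adjusted p = 5.06e-07; adjusted p = 0.105 with an estimated correlation), spliceosome (8.1e-05; adjusted p = 0.105 with an estimated correlation), DNA replication (0.000283; adjusted p = 0.0587 with an estimated correlation) and mitosis (0.00406; adjusted p = 0.326 with an estimated correlation) also lay lower, and detoxification targets higher (0.0239; adjusted p = 0.176 with an estimated correlation). Adjusted over the list alone, 1 gene was lower in each of the first 4, and 3 detoxification targets were higher.

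The compounds differed directly at the matched dose and time. Against BPK9, BPK29 raised HMOX1 by 1.04 ± 0.0324, ASNS by 1.02 ± 0.0378, CYP1B1 by 0.85 ± 0.0354 and the noncoding RNA NEAT1 by 1.07 ± 0.09, and lowered MCM7 by -0.63 ± 0.0216 and the imprinted gene MEST by -1.08 ± 0.0269. The mean of the aryl hydrocarbon receptor targets was higher with BPK29 by 0.46 (95% interval 0.43 to 0.50), that of ATF4 genes by 0.26 (0.23 to 0.28) and that of immediate early genes by 0.28 (0.24 to 0.31). The mitosis mean was lower by a difference of -0.25 (-0.29 to -0.21) and the heat shock mean by -0.22 (-0.24 to -0.19). The NRF2 target lists differed by 0.087 (0.072 to 0.102) for glutathione, -0.052 (-0.08 to -0.024) for NADPH and 0.029 (0.005 to 0.053) for detoxification. The NADPH and detoxification medians were -0.04 and -0.01, but 0.02 and 0.04 after rescaling to a common total. Camera called none of these NRF2 lists. Intervals that include 0 were those of ribosome biogenesis (-0.03, -0.06 to 0.01; 3 higher and 8 lower, or 4 and 2 after rescaling to a common total), the spliceosome (-0.00, -0.03 to 0.03; 6 and 6, or 8 and 1) and metallothioneins (-0.09, -0.19 to 0.01). Camera called 10 lists in this comparison. DNA replication (1 higher and 21 lower of 27, adjusted p = 1.15e-05) and immediate early genes (11 and 1 of 15, 2.34e-05) were called with an estimated correlation too, at 0.0495. With an estimated correlation the camera adjusted p was 0.0587 for ATF4, endoplasmic reticulum chaperones, aryl hydrocarbon receptor targets and cholesterol synthesis, 0.0698 for heat shock, 0.0724 for autophagy, 0.0784 for mitosis and 0.11 for NF-kB. Limma called 5379 of 11461 genes at an adjusted p under 0.05, 2258 higher and 3121 lower, and 219 by at least 1.5 fold. The share of higher calls was 42.0%, against 61.1% after rescaling to a common total (3445 and 2197) and 59.3% with voom (3596 and 2467).

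**Figure D4:**
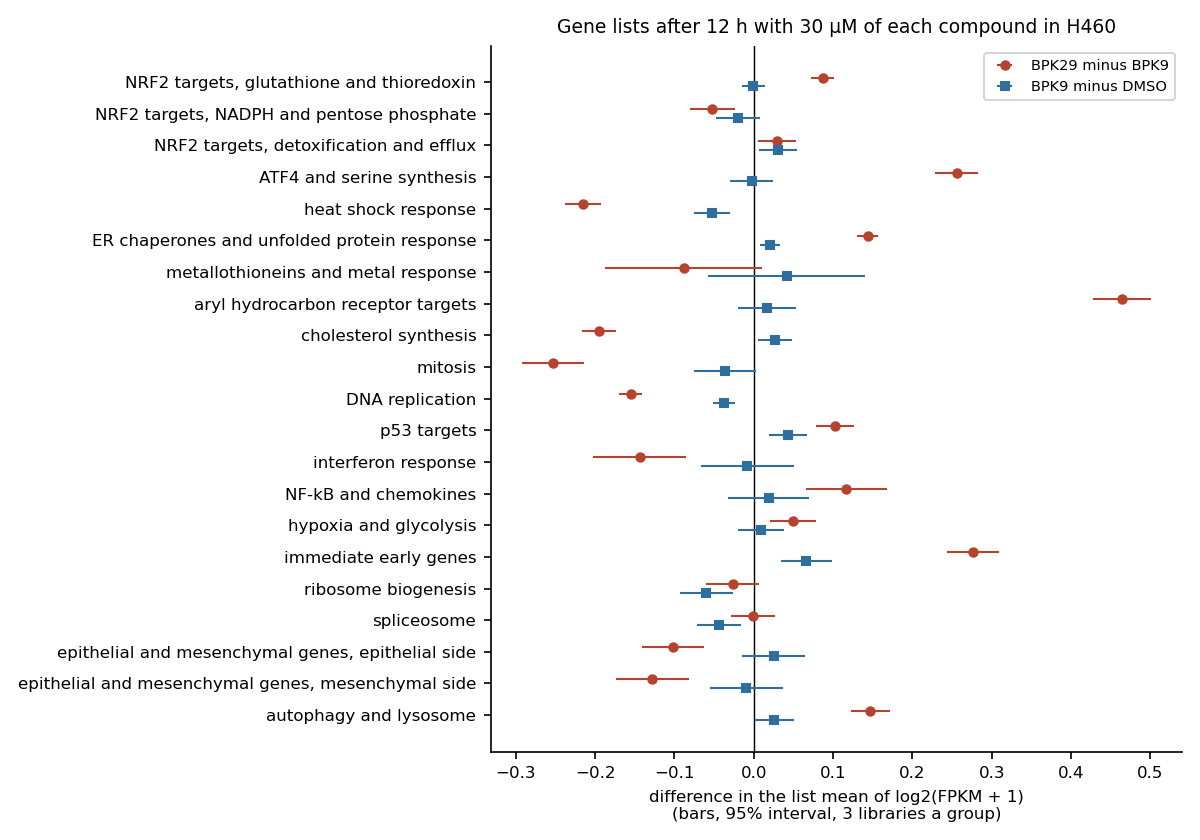
Difference in the mean log2(FPKM + 1) of each gene list (x axis) between BPK29 and BPK9 and between BPK9 and DMSO, with lists on the y axis and lines for the 95% interval over 3 libraries a group. Aryl hydrocarbon receptor targets lie at 0.46 for BPK29 against BPK9 and at 0.02 for BPK9 against DMSO.

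Changes after the compounds overlapped only in part with those after knockdown. NR0B1 knockdown and BPK29 had 953 higher genes in common, against 768 for independent lists (odds ratio 1.55, 95% interval 1.41 to 1.71). Lower in both were 1629, against 1267 (1.92, 1.77 to 2.09). Among 10929 genes, 857 and 721 went opposite ways, against 1069 and 910. The carboxypeptidase CPA4 (-2.21 after knockdown and -1.14 after BPK29), CTGF (-1.46 and -0.65) and the transcriptional inhibitor ID1 (0.73 and 1.07) were among the shared genes. NRF2 knockdown in H460 and BPK29 had 1175 higher genes in common, against 945 (odds ratio 1.66, 1.52 to 1.83). Lower in both were 1748, against 1337 (2.08, 1.92 to 2.27), while 1044 and 727 went opposite ways, against 1316 and 960. At a minimum of 1.5 fold, the odds ratios for NRF2 knockdown were 2.5 (1.48 to 4.13) for higher genes and 1.2 (0.753 to 1.86) for lower genes, the latter not passing the test. At this fold, more genes went opposite ways after NRF2 knockdown and BPK29 (69) than the same way (50), with 56 higher after knockdown and lower after BPK29, against 21.9 for independent lists. For NR0B1 knockdown the odds ratios were 3.58 for higher genes (15 in common) and 3.01 for lower genes (27 in common), while 15 and 9 went opposite ways, against 9.12 and 5.67. Across genes, which are not independent replicates, Pearson's r with BPK29 was 0.127 for NR0B1 and 0.107 for NRF2 knockdown. NR0B1 knockdown and BPK9 had 0 called genes in common, where BPK9 had 1 call. BPK29 and BPK9 shared that 1 gene, and their fold changes against the same DMSO libraries had an r of 0.357, beside 0.505 in simulated unchanged groups, and a covariance of 0.00771, beside a simulated 0.00234 (difference 0.00537). Part of this may come from the shared controls, and fits that split the DMSO libraries between the compounds were not run.

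The NR0B1 ChIP in H460 gave 13325 peaks in the authors' list, in hg19 coordinates per the submitters' processing notes. Every peak is 339 bp wide, no peaks overlap, and together they cover 4517175 bp, with a median distance to the nearest other peak of 42193 bp. Chromosome 1 held 1398 of them (10.5%), chromosome 2 held 1192, chromosome 5 held 889 and chromosome 7 held 836. Peaks were not assigned to the genes above, since no annotation of hg19 was at hand. There is no replicate of the ChIP or the input.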

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

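The look at a weaker knockdown for NQO1 below was chosen after the result was seen. The scaling test was chosen before, except for its voom value. A difference between the lines in their response to NRF2 knockdown, tested with limma's interaction term, is what brought up each result here. It was found for 9168 genes. Of these, 1372 genes were called in opposite directions in the lines, and 83 of those by at least 1.5 fold in both, such as CHAC1, PLAU and CXCL1. Higher in H2122 and lower in H460 were 801, against 2041 for independent lists, and 571 went the other way, against 1712. Among 100 splits of the libraries only the real one gave as many as 9168 genes in the interaction test. The highest count of the others was 6766. Every other split mixed knockdown and control libraries in at least one line, so these counts do not test whether the lines respond alike. NR0B1 fell further in H2122 (difference -1.05), as did NFE2L2 (-0.439) and KEAP1 (-0.525). Members of the NRF2 lists called in opposite directions were ABCC2 (-1.94), NQO1 (-1.19), ABCC3 (1.13), SLC7A11 (-0.78) and ALDH3A2 (0.651).

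NQO1 is the most abundant of these. It went from 837 to 871 FPKM down to 462 to 465 FPKM in the H2122 libraries, and from 1245 to 1289 FPKM up to 1547 to 1590 FPKM in the H460 libraries. A weaker knockdown of NFE2L2 in H460 would by itself give a smaller fall, while the log2 fold change was 0.311. This rise is part of the result to be explained, so it is no separate test of that cause. Library scaling is argued against. The log2 fold change in H460 was 0.309 with median-ratio scaling and 0.403 after rescaling to a common total, both set beforehand. With voom, added later, it was 0.272. What stays open is the line against the time of sampling (24 h in H2122, 72 h in H460), which cannot be told apart in this design.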

How the results depend on the processing

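The tests with voom and with each gene's own length were chosen after the data were seen; the others were set beforehand. Among values of named genes, 16065 kept their call and its direction or were called in neither fit, 64 became weaker and 42 stronger. The direction of values called in neither fit was not compared. Among list tests 2272 kept their call and its direction or were called in neither fit, 80 became weaker and 25 stronger. Values that reversed were ESRRA in H2122 (-0.00410 with median-ratio scaling), SNW1 after NR0B1 knockdown (0.12) and after BPK29 (0.0652) with rescaling to a common total, and CYP1A1 (-0.51), KDR (0.23) and COL3A1 (-0.39) in the difference between lines with voom; the cause was not tested.

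A minimum fold of 1.5 left 4891 genes for H2122 NRF2, 3746 for H460 NRF2, 1683 for NR0B1, 1469 for SNW1, 271 for BPK29, 219 for BPK29 against BPK9 and 3629 for the difference between lines; by construction this calls fewer genes. With it, the odds ratio of genes lower after H460 NRF2 knockdown and BPK29 was 1.2, and BPK29 and BPK9 shared 0 lower genes. Other odds ratios grew by over 1.5 times: NR0B1 with SNW1 from 5.04 to 13.6 (higher) and from 4.78 to 8.09 (lower), NRF2 with SNW1 from 3.07 to 5.37 and from 3.05 to 4.89, NR0B1 with BPK29 from 1.55 to 3.58 and from 1.92 to 3.01, and NRF2 with BPK29 from 1.66 to 2.5 (higher); the cause was not tested.

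The BPK9 count of 1 became 2 without a filter, with median-ratio scaling or with only the groups compared, 9 with rescaling to a common total, 57 with own lengths and 238 with voom. Leaving out single libraries gave 1 to 2, with 2 without DMSO replicate 1 or BPK29 replicate 3. Higher genes shared by BPK29 and BPK9 numbered 1 without a filter, and 0 to 1 on leaving out single libraries (1 without DMSO replicate 1). Lower ones numbered 0 to 1 (0 without DMSO replicate 1 or BPK29 replicate 1). The cause was not tested.

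With an estimated correlation, camera called 1 list for H2122 NRF2, 2 for H460 NRF2, 0 for NR0B1, 0 for SNW1, 2 for BPK29, 0 for BPK9, 2 for BPK29 against BPK9 and 4 for the difference between lines, against 11, 13, 9, 8, 12, 7, 10 and 13; the cause was not tested. Leaving out single libraries gave 9543 to 9882, 9095 to 9500, 7776 to 8303, 7482 to 7992, 4997 to 5831, 4592 to 5367 and 8644 to 9206 called genes, in the order used for the minimum fold. Replicate numbers gave little sign of pairing between groups (21 correlations from -0.109 to 0.126). The highest were 0.126 for H2122 shNRF2, 0.108 for H460 shNR0B1, and 0.105 and 0.103 for H460 shSNW1, each with shGFP. A weak pairing is therefore not excluded. For the peaks, 5 alternatives were not run, as all scores are equal and no hg19 annotation was at hand.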

Other observations

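The tests of gene lengths in another gene order, of different expression and of lower NR0B1 mRNA below were chosen after the results were seen. Splitting 3 against 3 libraries gives only 10 splits, too few for a share under 0.05. The real split and the highest other gave 10228 and 0 genes for H2122 NRF2 knockdown, 9532 and 0 for H460 NRF2 knockdown, 8337 and 0 for NR0B1, 8020 and 0 for SNW1, 5777 and 0 for BPK29, and 5379 and 1 for BPK29 against BPK9, with 1 split as large in each. For BPK9, 2 splits gave as many, with 1 gene in the real split and 1 in the highest other.

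FPKM levels in the compound columns differ gene by gene from those in the knockdown columns of H460. HDGF, a growth factor gene, was divided by 27 bp in the compound columns and by 2798 bp in the knockdown columns. Different expression is argued against as the whole cause, since RPM (reads scaled to a common library total) of shGFP replicate 1 and DMSO replicate 1 correlated with a Pearson's r of 0.958 across genes. The lengths were also compared with gene spans in RefSeq, a gene catalogue, which was not set beforehand. Log lengths correlated with log spans for the knockdown columns (Pearson's r 0.583 over 11259 genes) but not for the compound columns (-0.013 over 11173). The compound columns are thus the ones whose lengths do not follow their genes. A candidate explanation is that the lengths were attached in another gene order. The row order and the genome order of the genes that own the lengths had a Spearman's rho of 0.833 over 1382 genes.

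In H460, 200 genes rose and 157 fell by at least 1.5 fold in all 3 knockdowns, among them CHGA, FGFRL1, HR, FURIN and BPNT1. Under every scaling run, 99.2% or more of them were called the same way in all 3, with no minimum fold. Rescaling to a common total shifted the median of all genes by 0.091 for NRF2, 0.127 for NR0B1 and 0.0957 for SNW1 knockdown. Shifts of this size lie below 1.5 fold. Genes picked at 1.5 fold could thus hardly lose their call, so the percentage is no separate evidence against library scaling. Lower NR0B1 mRNA as the common cause is argued against by a log2 fold change of 0.327 for NR0B1 in the SNW1 knockdown. Whether the shGFP libraries stand apart from other libraries of the line stays open: the DMSO libraries, from the separate compound experiment, lie at 0.494 of the way from shGFP to the knockdown mean. The 95% bootstrap interval of 0.388 to 0.586 resamples genes, which are not independent replicates. The single DMSO libraries lie at 0.513, 0.493 and 0.444. Single genes differ, with 0.568 for CHGA, 1.01 for FGFRL1, 0.757 for HR, 0.957 for BPNT1 and -0.323 for FURIN. Of all replicates, H460 shGFP replicate 3 lay furthest from its partners, with a chi-square per degree of freedom of 5.99 and 4.68 between recovered reads. The next highest pair was H460 shNR0B1 replicates 1 and 2, at 2.54. Without shGFP replicate 3, limma called 9451, 8297 and 7941 genes for NRF2, NR0B1 and SNW1 knockdown. Of the genes shared by all 3 knockdowns, 318 were tested in H2122, which has its own shGFP libraries. After NRF2 knockdown there, 283 were called the same way and 18 the opposite way. Of all 10731 genes tested in both lines, 6306 were called the same way and 1372 the opposite way. The shared genes were picked partly by their change after H460 NRF2 knockdown, so this agreement can follow from NRF2 knockdown alone. It cannot tell whether the H460 shGFP libraries are a cause of what NR0B1 and SNW1 knockdown share. After BPK29, 143 of 335 of the shared genes were called the same way and 54 the opposite way. An effect of the GFP hairpin itself in both lines is left open by the H2122 values. A response common to the hairpins could not be tested with 1 control hairpin.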
